A study of Mus musculus with 101 samples.

How the data were processed

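DNA methylation was measured by enzymatic methyl sequencing (EM-seq), which converts unmethylated cytosines with enzymes in place of bisulfite, after hybrid capture with a Twist targeted panel. The samples were mouse embryonic stem cell lines derived from Diversity Outbred stock, an outbred population descended from several inbred founder strains. Per the labels, the lines were grown in serum and LIF with 2i, a pair of kinase inhibitors that hold the cells in a naive pluripotent state. The labels listed 101 libraries, of which 16 carried the suffix WA and the name of a line that also had an unsuffixed library.

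The authors deposited a table of average methylation fractions for 868 target regions and a table of methylation fractions for 7917 CpGs, each with 85 columns. Each region carried 1 of 11 category names given by the authors, which are used here as written. Per the submitters' processing notes, Trim Galore 0.6.4, Bismark, Bowtie2 and the mouse assembly mm10 were used; their roles, order and settings are not given in the sources used here. Both tables were filtered at a coverage of 10 per the deposited tables' own names, and what the filter was applied to is not given in the sources used here. The tables hold no read counts, so the depth behind each value is unknown and no counting interval was computed. A value from few reads and one from many could not be told apart, and sampling noise adds to each spread between lines given below. All deposited fractions are reported as percent, and differences between them as percentage points.

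Columns were matched to titles by name. Of the 85 columns, 44 matched 1 title. The other 41 were used only as members of their prefix group: 16 named lines with 2 titles, 24 carried a final N that the title lacked, and 1 matched no title. For the 16 lines with 2 titles, which library a column holds, or whether it combines both, is not given in the sources used here. The planned comparisons of WA libraries with their partners, and the planned test of repeat libraries of a line, were therefore not run. The prefix of the line name (B1, B2, B3A or B3B) was the remaining grouping, and its meaning is not given in the sources used here. No columns were identical, and each was treated as a line. Where nothing says that columns came from separate cultures, p-values measure the spread between these columns.

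Regions with a value in at least 80% of lines were kept, which left 787 regions and set aside 81, of which 23 had no value in any line. A value was present in every line at 621 regions. Lines lacked between 25 and 173 regions, with a median of 58. Region averages recomputed from the CpG table correlated with the deposited averages at r = 0.967 across values, with a mean absolute difference of 2.79 points. Gene names came from a RefSeq gene table of the assembly GRCm38.p6, whose coordinates are those of mm10. The table has no exons or strand, so a region is described as overlapping a gene or by its nearest gene; 769 regions overlapped a gene and a further 76 lay within 5 kb of one.

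Differences between prefixes were tested per region with the moderated F test of limma 3.58.1 in R 4.3.3 on log2((fraction + 0.01)/(1 - fraction + 0.01)), with Benjamini-Hochberg adjustment and a threshold of 0.05. On simulated data for this comparison, with 787 regions and 200 of them shifted in 1 prefix, the test recovered 76 of 100 regions shifted by 1 on the log2 odds scale and 99 of 100 shifted by 2, with 9 false calls. Each simulated region varied on its own, whereas the regions of a real library share a level. The 9 false calls therefore do not measure false calls in the real comparison. Single values per line were compared by two-sided permutation tests with 100000 resamples, paired values by sign-flip permutation, and correlations by permutation of 1 measure. The smallest p these tests can give is 1e-05. Sets of regions were compared with 100000 random sets matched on mean methylation in 5 bins, where the smallest two-sided p is 2e-05. Random sets treat regions as independent, so their p can be too small where the regions of a set vary together. On simulated data for the spread comparison, 9 of 100 unchanged sets of 23 regions passed 0.05, and all 100 sets with the SD multiplied by 0.8 did. These sets were drawn at random from other regions, so they do not measure false calls for loci that co-vary. For pairs of loci, 0 of 171 pairs were called among simulated independent loci and 170 of 171 among loci that shared a factor. These computations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots were drawn with matplotlib 3.10.9.

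Imprinted loci, gene lists, tests and most alternatives were fixed before the data were examined. The target regions covered 20 of 26 listed imprinted loci: 16 listed as maternally methylated, 3 as paternally methylated and 1 somatic. Where several regions fell in a locus, their mean was used. The Zdbf2 interval had been listed with the maternal class; it is usually described as a paternally methylated region that arises after fertilisation, while the maternal germline mark lies at the neighbouring Gpr1 promoter. The list was kept as fixed, and an added alternative used the Gpr1 region in its place. Named regions were the covered imprinted loci, the 10 other regions with the largest SD between lines, the 10 regions with the smallest F test p between prefixes, and up to 4 regions with the largest SD from each gene list. The rule for the largest SD had been written for regions that passed the test of repeat libraries; as that test was not run, all kept regions outside the imprinted loci were used. Alternatives covered the logit offset, the scale, centring by the library mean, recomputed region averages, filters on missing values and CpG number, the measure of spread, the locus summary and lines left out.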

Results

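Methylation was read at captured target regions in 85 naive mouse embryonic stem cell lines from Diversity Outbred stock, with the stated aim of measuring how variable it is among lines. By prefix of the line name there were 28 B1, 18 B2, 20 B3A and 19 B3B lines. The region table gives fractions without read counts, so the depth of each library is unknown. Coordinates are those of mm10.

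Methylation was low at most target regions and varied widely from line to line. The mean over the 787 kept regions was 19.01% ± 10.1 (SD, n = 85 lines) and ranged from 3.02% to 43.8%. The 3 kept regions of pluripotency genes were almost unmethylated in these lines. At Nanog, a core transcription factor of pluripotency, the region nearest the gene (chromosome 6, 122706796 to 122707321) had 0.360% ± 0.599 (SD, n = 85). The regions overlapping Zfp42, a marker of naive cells also known as Rex1, and Tbx3 had 0.792% ± 1.44 (SD, n = 80) and 0.191% ± 0.381 (SD, n = 83). The other listed pluripotency gene covered, Dppa3, had a higher 6.26% ± 6.47 (SD, n = 64) at a region left out of the kept set for missing values. Regions of the 2-cell stage category had the highest median of the 11 categories, 29.7% over 46 kept regions. The medians were 21.7% for germline_GGD, 21.4% for imprinting, 17.5% for Cancer, 16.7% for germline_Dahlet, 16.2% for B6J vs 129, 15.2% for aging_Meer and 13.4% for Lineage-associated. They were 4.58% for aging_Young and 4.56% for aging_shared, where 64 of 127 and 6 of 11 kept regions had a mean under 5%.

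The regions with the largest spread between lines outside the imprinted loci came from germline, 2-cell stage, cancer and aging categories. Their values ran from near 0% to near full methylation. Ctag2l1 (chromosome X, 74481149 to 74481649) had the largest SD, with 39.9% ± 25.7 (SD, n = 73) and a range of 0% to 100%. Usp26, a deubiquitinase gene on chromosome X, followed with 43.8% ± 25.7 (SD, n = 68). Both were among the regions missing from some lines. Regions overlapping Gm5576, Igbp1b, Nfia, Eif4a3l2, Abcb5, Slc3a1, Gm18765 and Esr1 completed the 10. At Esr1, the gene of estrogen receptor alpha (chromosome 10, 4620965 to 4621465), the mean was 40.8% ± 23.8 (SD, n = 85) with a range of 3.40% to 92.8%. The Pearson r of these 10 regions with the mean of the other regions lay between 0.852 at Usp26 and 0.976 at Esr1. No test separated line differences from the error of a repeat library, because the repeat libraries could not be assigned to columns.

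Regions of most categories followed the overall level of a line. The median r with the mean of the other regions was 0.910 for Cancer, 0.908 for aging_Meer, 0.904 for germline_GGD, 0.901 for 2-cell stage and 0.892 for germline_Dahlet. It was 0.841 for Lineage-associated, 0.830 for imprinting, 0.798 for aging_Young, 0.791 for aging_shared and 0.761 for B6J vs 129. These medians are not matched for level, and aging_Young and aging_shared have low median levels. Only for B6J vs 129 was this r tested, against regions of similar mean; the closing section gives that test. Among the B6J vs 129 regions that followed it least were those of Lhx9 and Nkx2-1, transcription factor genes of gonad and forebrain or lung development, with 14.2% ± 16.9 and 18.2% ± 15.6 (SD, n = 85 each); these were named after their values were seen. The nearly unmethylated nPSC-associated regions had a median r of 0.153.

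**Figure D1:**
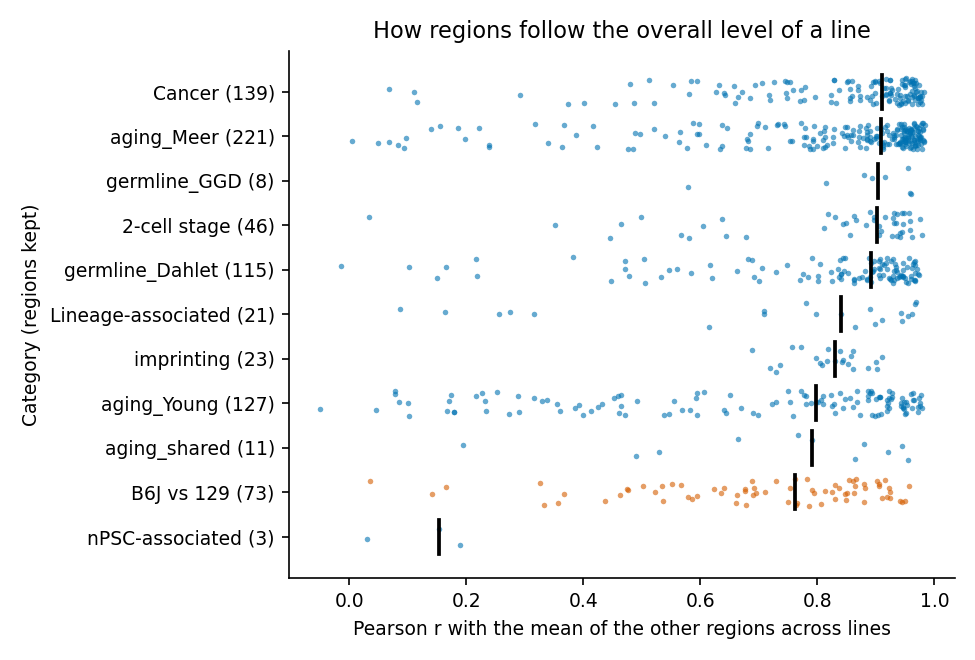
Pearson r across lines between each kept region (points) and the mean of the other kept regions (horizontal axis), by category with its number of kept regions (vertical axis); black bars are medians and B6J vs 129 is in orange. The medians lie between 0.153 for nPSC-associated and 0.910 for Cancer.

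The gene lists differed in level and spread. The median SD between lines was 18.8 points over 2 regions of methylation machinery genes, 13.7 over 29 of imprinted genes, 10.1 over 20 of germline genes, 2.69 over 7 of lineage genes and 0.599 over 3 of pluripotency genes, with no test between lists. The examples below had the largest SDs of their lists. Among germline genes, Dpep3 had 42.1% ± 21.5, Taf7l 39.2% ± 16.9, Tuba3a 25.3% ± 16.1 and Asz1 28.9% ± 15.98 (SD, n = 85 each). Regions overlapping Tet3, a dioxygenase that oxidises 5-methylcytosine, and Dnmt3l, a cofactor of de novo methylation, had 56.2% ± 20.6 and 28.8% ± 17.1 (SD, n = 85). Among lineage genes the levels fell far apart. A region of Pax6, a regulator of eye and neural development, had 56.7% ± 20.7 (SD, n = 84), whereas regions of Gata4, Foxa2 and Sox17, transcription factors of endoderm, had 13.9% ± 7.83, 7.75% ± 4.26 and 5.03% ± 2.69 (SD, n = 85 each).

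Lines of prefix B1 were the most methylated and lines of B3A the least. The library mean was 24.5% ± 9.26 (SD, n = 28) in B1, 20.7% ± 8.44 (SD, n = 18) in B2, 12.8% ± 7.75 (SD, n = 20) in B3A and 15.8% ± 10.5 (SD, n = 19) in B3B. These means differed between prefixes (permutation test of the F statistic, p = 0.00019), while the ranges of the lines overlapped. Among the 6 pairwise two-sided permutation tests, B1 exceeded B3A by 11.7 points (p = 9e-05, adjusted p = 0.00054), B1 exceeded B3B by 8.64 points (p = 0.00546, adjusted p = 0.0109) and B2 exceeded B3A by 7.90 points (p = 0.0054, adjusted p = 0.0109). B1 and B2, B2 and B3B, and B3A and B3B did not differ past the threshold (adjusted p = 0.205, 0.196 and 0.315). The final N was unevenly spread over the prefixes, with 16 of the 20 B3A columns carrying it. The order held B1 highest and B3A lowest in columns without a final N. Their means were 24.1%, 20.7%, 8.34% and 15.005% for B1, B2, B3A and B3B, over 22, 18, 4 and 10 lines (permutation p = 0.00784). Columns with the final N, none of them B2, had means of 25.9%, 13.9% and 16.8% for B1, B3A and B3B, over 6, 16 and 9 lines (permutation p = 0.0268). Lines with 1 title had means of 23.1%, 18.4%, 13.2% and 14.5% (permutation p = 0.00175). In the 16 lines with 2 titles the means were 30.8%, 28.8%, 11.4% and 22.8% over 5, 4, 4 and 3 lines, a difference that did not pass the threshold (permutation p = 0.0855).

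**Figure D2:**
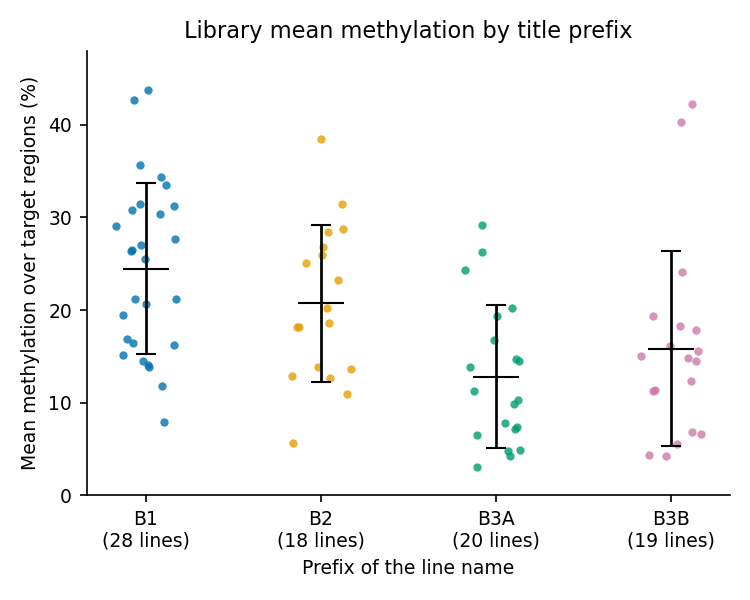
Mean methylation over the kept target regions in percent (vertical axis) for each line (points), by prefix of the line name; black bars give the mean and SD. B1 lines average 24.5% and B3A lines 12.8%, with overlapping ranges.

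B1 had the highest mean at each of the 10 regions with the smallest p, and B3A the lowest at 9 of them. Morc1, a gene of germ cell transposon silencing, had the smallest p, with 10.6% ± 9.34 (SD, n = 28) in B1, 5.55% ± 6.15 (SD, n = 18) in B2, 1.27% ± 1.17 (SD, n = 20) in B3A and 4.15% ± 5.996 (SD, n = 19) in B3B. At Tnfrsf1a, which encodes a tumour necrosis factor receptor (chromosome 6, 125360138 to 125360638), the means were 34.9% in B1, 25.3% in B2, 9.12% in B3A and 20.6% in B3B, with SDs of 17.1, 16.7, 7.83 and 15.4. Both passed the limma F test with Benjamini-Hochberg adjustment (adjusted p = 3.05e-05 and 3.52e-05). A pair of regions in Irak3, a negative regulator of Toll-like receptor signalling, stood at 23.3% and 18.98% in B1, 13.2% and 11.3% in B2, 3.24% and 2.29% in B3A and 3.13% and 3.46% in B3B. The other regions among the 10 smallest p overlapped Asap3, Gm41005, Tdpoz3, D630039A03Rik, Stard13 and Trp53i11. The library mean was also used as a covariate in limma. For this covariate, here and below, it was averaged over regions on the log2 odds scale of the test. With it, Morc1 (adjusted p = 0.0371) and Tnfrsf1a (adjusted p = 0.0436) passed. The other 8 did not, with adjusted p between 0.0530 at Asap3 and 0.172 at Trp53i11. Centring the fractions by their library mean ended the calls at Morc1 (adjusted p = 0.355), Asap3, D630039A03Rik, Trp53i11 and both Irak3 regions.

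In all, 642 of 787 regions differed between prefixes (limma F test, adjusted p under 0.05), with B1 highest at 571 of them and B3A lowest at 597. Of the 23 called regions of the imprinting category, which co-vary, B3A was lowest at 4; whether this differs from other regions was not tested. All 29 regions of imprinted genes were called (29 adjusted over the list alone), as were 17 of 20 regions of germline genes (18 adjusted over the list alone), 6 of 7 of lineage genes (6 adjusted over the list alone) and 2 of 2 of methylation machinery genes (2 adjusted over the list alone). None of the 3 regions of pluripotency genes was called by limma, and 0 were when adjusted over the list alone; the smallest adjusted p was 0.560, at Zfp42. Magel2, Gnas and Peg10 regions of the Cancer category had the largest SDs among imprinted genes together with Peg13, with means of 30.7%, 31.7%, 56.9% and 38.2%. With the library mean as a covariate, an alternative chosen after seeing the data, 27 regions were called; by the means as deposited, B1 was highest at 11 and B3A lowest at 21 of them. Of the lists, 2 of 29 regions of imprinted genes, 1 of 20 of germline genes, 1 of 7 of lineage genes and 0 of 2 of methylation machinery genes were then called by limma. Centring each library by its mean gave 608 calls, of which 476 were among the 642. The share of called regions with B1 highest went from 88.9% to 38.98%, and that with B3A lowest from 92.99% to 35.9%. This follows at least in part from the centring, which lowers every region of a line by the same value and so lowers B1, with the highest library mean, the most. Under the covariate the smallest adjusted p was at 4933404O12Rik and Timm8a2 (0.00511 for each), which were named after their values were seen. At 4933404O12Rik, not called without the covariate (adjusted p = 0.112), B3B was highest with 13.8% ± 14.95 (SD, n = 19) and B2 lowest with 7.62% ± 9.13 (SD, n = 18). Timm8a2 had 24.7% ± 13.2 (SD, n = 28) in B1, 27.4% ± 13.9 (SD, n = 18) in B2, 12.2% ± 8.39 (SD, n = 20) in B3A and 17.9% ± 14.6 (SD, n = 19) in B3B.

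Imprinted loci, which carry methylation on 1 parental copy in somatic cells, lay well below the intermediate level that 1 methylated copy gives in most lines. Over 19 germline loci the mean was 24.1% ± 12.7 (SD, n = 85), from 1.095% in the lowest line to 51.3% in the highest. Peg13 had the highest mean, 38.2% ± 19.2 (SD, n = 85), followed by the H19 control region with 31.2% ± 15.5 and the Dlk1-Meg3 intergenic region with 28.03% ± 11.3 (SD, n = 85 each). Impact had the lowest, 19.1% ± 15.4, then Plagl1 with 19.7% ± 12.7 and Inpp5f with 20.1% ± 13.1 (SD, n = 85 each). Kcnq1ot1, Nespas, Snrpn and Igf2r had 27.7%, 27.4%, 27.3% and 26.3%, and Mest, Peg3, Zdbf2, Peg10, Grb10, Nnat, Rasgrf1, Nap1l5 and Zrsr1 lay between 23.6% and 20.2%. The Meg3 promoter, a somatic imprinted region, had 20.5% ± 10.8 (SD, n = 85), and the Gpr1 region, which the list did not hold, 17.2% ± 14.7 (SD, n = 85).

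Loss below 25% was common and gain above 75% rare. Of 1612 values of a locus in a line, 866 (53.7%) were under 25% and 4 were over 75%. The 4 high values were all at Peg13, where the highest line reached 84.4%. The number of lines under 25% ran from 27 at Peg13 and 28 at H19 to 57 at Plagl1 and 58 at Impact and Zdbf2. In 16 lines every locus with a value was under 25%, in 13 lines none was, and 56 lines had some loci on each side. The imprinted mean was 31.2% ± 10.5 (SD, n = 28) in B1, 26.1% ± 11.007 (SD, n = 18) in B2, 18.997% ± 11.6 (SD, n = 20) in B3A and 16.9% ± 12.9 (SD, n = 19) in B3B (permutation p = 0.00014). Each locus except Peg13 (adjusted p = 0.0692) differed between prefixes by permutation with Benjamini-Hochberg adjustment over the 19 loci. Peg13 was called by the limma F test (adjusted p = 0.0407), so its call depended on the test. With the library mean as a covariate, limma called 2 of 19 regions of the loci listed as maternal. It called 0 of 4 regions of those listed as paternal.

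**Figure D3:**
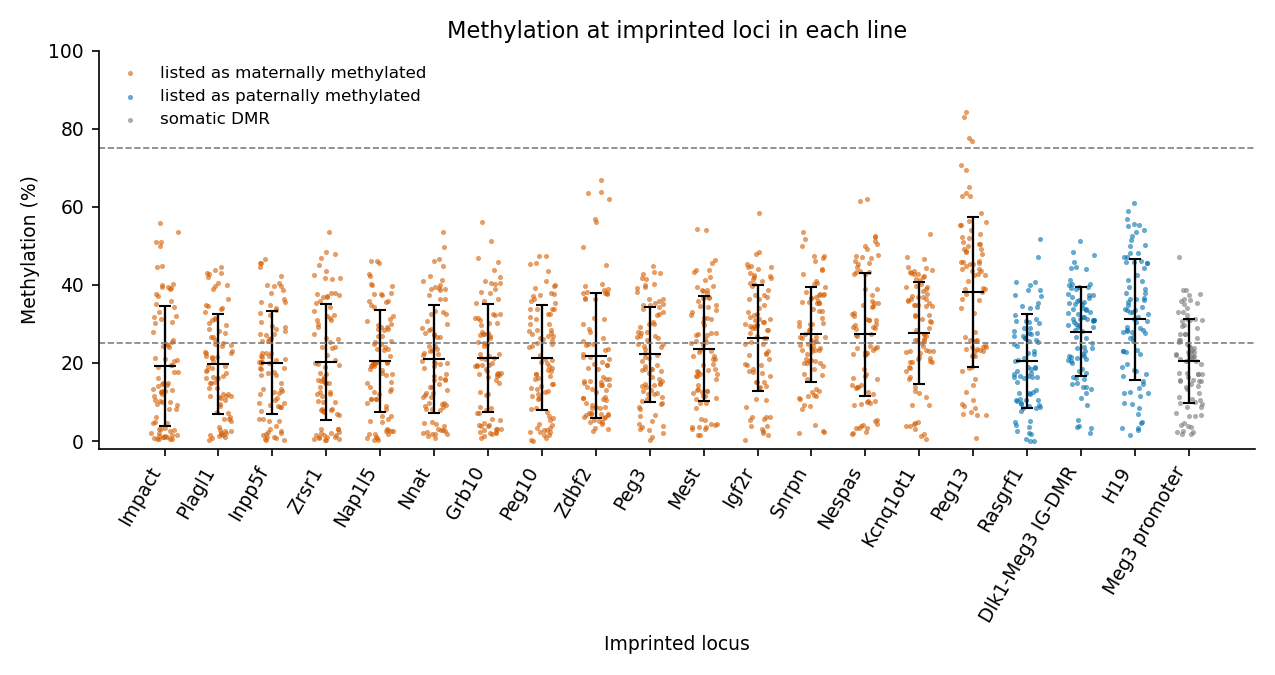
Methylation in percent (vertical axis) at each imprinted locus (horizontal axis) in each line (points), coloured by class as listed beforehand; black bars give the mean and SD and dashed lines mark 25% and 75%. Locus means lie between 19.1% at Impact and 38.2% at Peg13, and the 4 points above 75% are at Peg13.

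The loci listed as paternally methylated had slightly more methylation than those listed as maternally methylated, and the call depended on H19. H19, the Dlk1-Meg3 intergenic region and Rasgrf1 averaged 26.6% ± 11.99 (SD, n = 85), against 23.6% ± 13.03 (SD, n = 85) over the 16 loci listed as maternal. The paternal mean was higher by 2.95 points ± 5.42 (SD of the difference, n = 85), in 60 of 85 lines (two-sided sign-flip permutation, p = 1e-05, the smallest it can give). The signs were flipped over lines, so this p-value concerns these loci in these lines. With 3 paternal loci it does not extend to the paternal class. Without H19 the difference was 0.692 points (p = 0.336), without the Dlk1-Meg3 intergenic region 2.19 points (p = 0.00099) and without Rasgrf1 5.98 points (p = 1e-05). With the median over loci in place of the mean it was 4.56 points (p = 1e-05). With the Gpr1 region in place of Zdbf2, an alternative added after the data were seen, it was 3.24 points (sign-flip p = 1e-05). The difference over all listed loci was 2.45 points in B1, 3.89 in B2, 1.72 in B3A and 4.11 in B3B, which did not differ past the threshold (permutation p = 0.452). The paternal mean was the higher in 13 of 28 B1 lines, 15 of 18 B2, 14 of 20 B3A and 18 of 19 B3B lines. Single loci departed from the mean of the other 18 in each direction. Peg13 was higher by 14.97 points in 77 of 85 lines, H19 by 7.48 points in 75 and the Dlk1-Meg3 intergenic region by 4.18 points in 62, and Plagl1 was above that mean in only 8 lines and Nnat in 9 (adjusted sign-flip p = 1.46e-05 for each of these loci). Mest and Zdbf2 did not depart from it past the threshold (adjusted p = 0.269 and 0.0516).

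The spread between lines at imprinted regions was slightly smaller than at other regions of similar mean. The median SD of the 23 imprinted germline regions was 13.7 points, against 15.3 for random sets of the 250 other regions in the same range of means (permutation p = 0.00016). Random sets treat regions as independent, whereas imprinted loci rose and fell together across lines. The p-values of this comparison can therefore be too small, and they do not measure the spread between lines. Peg13, with an SD of 19.2 points, and the Dlk1-Meg3 intergenic region, with 11.3, marked the ends of the locus values. The direction turned on the logit scale, where the median SD was 1.499 against 1.35 (p = 0.00648), and for the interquartile range, 21.4 points against 20.2 (p = 0.0574). Without matching on the mean, the imprinted median SD was above that of other regions, 13.7 against 11.1 points (p = 0.561).

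Lines with low methylation at other target regions also had low methylation at imprinted loci. The mean of the 19 loci correlated with the mean of 760 other regions at Pearson r = 0.893 and Spearman rho = 0.897 over 85 lines (permutation p and adjusted p over the 9 correlations 1e-05 for r, 1e-05 and 1.12e-05 for rho). Without the 2 lines farthest from the median of the other regions, r was 0.886. Within prefixes r was 0.847 in B1, 0.891 in B2, 0.874 in B3A and 0.930 in B3B, and rho was 0.842, 0.851, 0.904 and 0.830. Without the 2 farthest lines of each prefix, r was 0.803, 0.833, 0.906 and 0.786. It was 0.855 over the 69 lines with 1 title, 0.967 over the 16 with 2 titles, 0.854 over columns with a final N and 0.916 over the others. By locus, r was highest at Zdbf2 (0.906), Nnat (0.894), Nespas (0.892) and H19 (0.882), and lowest at Peg13 (0.681), Snrpn (0.710) and Kcnq1ot1 (0.749).

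**Figure D4:**
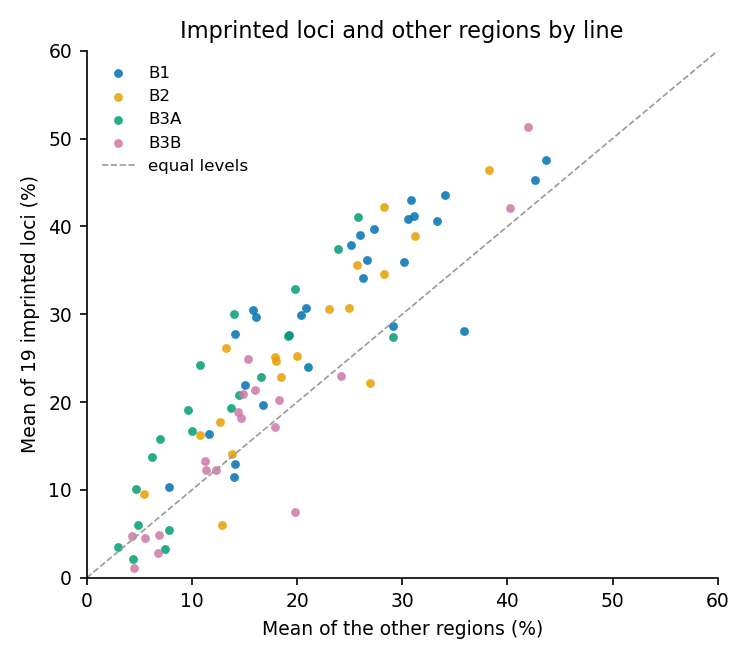
Mean methylation of the 19 imprinted germline loci (vertical axis, %) against the mean of the other kept regions (horizontal axis, %) for each line, coloured by prefix; the dashed line marks equal levels. Points rise together with r = 0.893, and the imprinted mean reaches 51.3%.

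Imprinted loci rose and fell together across lines. All 171 pairs of the 19 loci correlated positively past the threshold (Spearman, permutation with Benjamini-Hochberg adjustment, 82 lines with a value at every locus), with a median rho of 0.853. Regions of most categories followed the overall level of a line, so positive pairs could arise at other regions too. No other set of regions was put through the pair test, here or in the alternatives below. Whether the co-variation is particular to imprinted loci is therefore unknown. The closest pairs were Nespas with Zrsr1 (rho = 0.956) and Nnat with Nespas (rho = 0.954), which lie on different chromosomes in the first case. The loosest were Zdbf2 with Peg13 (rho = 0.589) and with Snrpn (rho = 0.619). After centring each library by its mean over regions, 141 pairs stayed positive past the threshold and 3 were negative. The negative pairs were Zdbf2 with Snrpn (rho = -0.271), Peg3 (rho = -0.240) and Kcnq1ot1 (rho = -0.230), with adjusted p = 0.0170, 0.0368 and 0.0450. When the mean of the other regions was instead removed by regression, an alternative chosen after seeing the data, 144 pairs were positive and 12 negative past the threshold. Each of the 12 paired Zdbf2 with another locus, the lowest being Igf2r (rho = -0.351, adjusted p = 0.00152).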

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

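The summaries in this part were chosen after the data were seen. Signal was present in parts of the tables that the comparisons did not use. The 135 CpGs that lie in no target region had a mean methylation of 26.97%, with an SD of 10.5 points between lines. The 7782 CpGs inside target regions had a mean of 11.99%.

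The 58 regions that had values but were set aside because too many lines lacked one had a mean of 33.4%, above the 19.01% of the kept regions. Of these, 19 belonged to B6J vs 129, 17 to 2-cell stage, 9 to germline_Dahlet and 8 to Cancer. Dppa3, which encodes a factor that limits maintenance methylation, was the member of the nPSC-associated category among them. The region nearest it had 6.26% ± 6.47 (SD, n = 64 lines).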

How the results depend on the processing

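Of 40 alternative values of the main results, 33 stayed on their side of the threshold in the same direction or, for counts, within 1.5 times the main count. Centring by the library mean gave 608 regions between prefixes, of which 476 were shared with the 642. It counted among the 33 through its number of calls alone. Subtracting a library mean that differs between prefixes can itself create differences, so this number does not show that the main calls held. B1 was highest at 237 of the 608 against 571 of the 642, but centring by construction lowers B1 the most, so this shows no change of direction. Removing the mean of the other regions by regression, added after the data were seen, gave 144 positive pairs of imprinted loci but 12 negative ones, all with Zdbf2. Regions with at least 5 CpGs gave 359 calls between prefixes among 431 tested, where fewer regions entered the test. The library mean as a covariate gave 27, of which 23 were among the 642 regions called without it; chosen after the data were seen, it removes by construction what a region shares with the rest of its library. The difference in spread at imprinted regions, -1.58 points, became 0.146 on the logit scale (in log2 odds), 1.24 points for the interquartile range and 2.62 points without matching; the cause was not tested. The paternal excess without H19 was 0.692 points, since H19 was the highest of the 3 loci averaged. With limits of 20% and 80%, 2 values lay over the high limit in place of 4. For the 10 named regions between prefixes and the imprinted loci, 115 alternative values counted as the same. For a named region this meant the same side of the threshold. For an imprinted locus it meant only that the mean moved by less than its SD between lines. Those SDs lay between 10.8 points at the Meg3 promoter and 19.2 at Peg13, so a locus could hardly fail and its label says little. The other 14, all at regions between prefixes, no longer passed the threshold, 8 of them with the library mean as a covariate and the rest with centring. Leaving out the 16 lines with 2 titles, leaving out B1dB37N and B2d2A for regions between prefixes, recomputed averages at imprinted loci, the Gpr1 region in place of Zdbf2, covariates for the name groups and regions with values in every line (for the library mean) were also added after the data were seen. No paired analysis was possible because the tables hold 1 column per line and do not say which of a line's 2 libraries it is. Alternatives for WA libraries and for repeat libraries were not run for that reason. A coverage of at least 20 was not run, as the tables give no coverage, and the unknown depth limits how far low and high fractions of single lines can be read.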

Other observations

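Tests chosen after the result was seen are those of lines with 2 titles, of missing regions and the final N between prefixes, of the covariate fit, of similar line names, of noise in the B6J vs 129 regions, and of the curve at imprinted loci with and without prefix terms. Lineage-associated regions ran from unmethylated to near the middle of the scale. Ehmt1 and Ehmt2, which encode histone H3 lysine methyltransferases, had 0.253% ± 0.282 and 0.585% ± 0.850, and Otx2 0.822% ± 0.625 (SD, n = 85 lines each). Musk, Pf4 and Calml3, genes of muscle, platelets and epithelium, had 48.8% ± 22.1, 48.2% ± 22.1 and 41.5% ± 22.3 (SD, n = 85 each). Among the germline_GGD genes, Dazl had 26.1% ± 13.9, Slc25a31 27.5% ± 13.4, Ddx4 9.87% ± 4.58 and Tex19.1 6.36% ± 5.27 (SD, n = 85 each). These examples were picked after their values were seen.

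Lines whose name also carried a WA-suffixed title had a higher library mean, 23.9% ± 12.4 (SD, n = 16) against 17.9% ± 9.18 (SD, n = 69), a difference of 6.08 points within prefixes (permutation p = 0.0137). The difference was 7.64 points in B1, 10.4 in B2 and 8.25 in B3B but -1.75 in B3A; these did not differ past the threshold (permutation p = 0.306). They lacked fewer regions, 33.4 against 69.4 on average. The number of missing regions and the library mean had r = -0.216 (permutation p = 0.0474) and rho = -0.192 (permutation p = 0.0783) over all 85 lines, and r = -0.153 (permutation p = 0.208) and rho = -0.148 (permutation p = 0.225) over the 69 lines with 1 title. The columns B1dB37 and B1dB37N, whose names differ by 1 letter, had the most similar profile of all 3570 pairs of lines after the library mean and the prefix mean were removed (r = 0.695). B2d2 and B2d2A had r = 0.179, a value reached by 90 of 892 pairs within prefixes.

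Prefixes differed at 642 regions and in the library mean. Of 100 groupings of the lines, the real one among them, only 1 gave as many regions, the real one, and the highest other gave 397. This ranks the real grouping first of 100, which makes a random grouping an unlikely source. It does not exclude chance, and nothing says that the columns of a prefix are independent. That a random grouping called so many regions points to a level shared by many regions of a library. With the library mean as a covariate the real grouping gave 27 and the highest of 99 others 24. The difference in library mean stayed after the number of missing regions was regressed out (permutation p = 0.00029), without the 16 lines with 2 titles (p = 0.00206) and when permuted within columns with and without a final N (p = 0.00017), which argues against each of these as the whole source. What the prefix stands for remains open, and no biological explanation was tested.

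Regions of the B6J vs 129 category varied between lines apart from the rest of the library. Their median r with the other regions was 0.753 over 71 regions, against 0.903 for matched random sets (permutation p = 2e-05), with the lowest values among regions of SD over 10 points at Lhx9 (r = 0.367), Nkx2-1 (r = 0.462) and Ccnb1ip1 (r = 0.475). Missing values do not account for it, since the permutation p was 2e-05 over regions with a value in every line. In the 17 of 71 regions with at least 4 CpGs a median share of 1 of the CpGs followed the rest. This argues against a variant at a single CpG in those 17 regions. The others, both Irak3 regions among them, had too few CpGs to be examined, so such a variant stays open there. Measurement noise stays open, since depth and fragment length are unknown and CpGs of a region can share fragments. In the 8 regions whose ends lay at least 400 bp apart, the median r between ends after the library mean was 0.782, with 7 over 0.3 and the lowest at -0.00526. The 2 pairs of neighbouring regions compared had r = 0.910 in Irak3 and 0.704 at Casq2. Neighbouring regions in Lhx9 were not compared in this way, and their r with the other regions was 0.594 and 0.367. The neighbours at Irak3 and Casq2 lay less than 400 bp apart, so shared fragments are not excluded there. Differences between founder strains may underlie this pattern, as a hypothesis that was not tested, because the tables hold no genotypes.

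Over all lines pooled, the imprinted mean levelled off in lines with a high mean elsewhere. The quadratic term was -1.41 points per squared SD (permutation p = 0.00842) and -1.36 with prefix terms in the model (p = 0.00796). Different levels of the prefixes therefore did not make it. The model gives all prefixes a shared slope and curve, so it cannot exclude pooling of prefixes that differ in these. Other regions matched on the mean had a median term of 0.663, against -1.42 at the 23 imprinted regions (random sets, p = 2e-05). The curve was fitted against the mean of the other regions, so the terms of those regions nearly cancel by construction. That comparison therefore cannot decide whether the curve is particular to imprinted loci. The highest line stood at a median of 53.4% at imprinted regions against 66.9% at matched regions (random sets, p = 2e-05). Random sets treat regions as independent, whereas imprinted loci rose and fell together, so both p-values can be too small. A candidate explanation is that imprinted loci stop near the level of 1 methylated copy. It stays open, since the term was -2.30 in B1 and -5.13 in B3A but 0.0565 in B2 and 0.0117 in B3B, and Peg13 exceeded 75% in 4 lines.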
